A study of Vitis vinifera with 2 samples.

How the data were processed

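Chromatin immunoprecipitation followed by sequencing (ChIP-seq) had been done on leaves of grapevine (Vitis vinifera) that overexpressed the transcription factor VlbZIP30. The protein carried a FLAG epitope in 3 copies and was driven by the CaMV 35S promoter, a strong viral promoter that is active in most plant tissues. Per the labels' protocols, plants aged 4 months were kept without water for 20 days, and the uppermost leaves were taken. There were 2 libraries, 1 precipitated with an anti-FLAG antibody and 1 control. The title of the control calls it input, while its antibody field names IgG. It is called the IgG control here, and which of the 2 descriptions holds could not be settled from the sources used here.

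The authors deposited 1 peak list, whose name sets FLAG against input; no other source used here says how the libraries entered the peak call. Per the submitters' processing notes, BWA, MACS2 and HOMER were used, with no role given; their versions, their settings, the genome build and the gene annotation are not given in the sources used here. Per the file headers, each peak has a position, a peak score given by the authors, an annotation class, a signed distance from the peak centre to the nearest transcription start site (TSS) and the identifier of that gene. The scale of the deposited score is not named. Its lowest value was 1.30142, just above 1.30103, which is -log10 of 0.05, and the 49173 peaks held 4185 distinct scores; the score was therefore used only to rank peaks and to compare medians within the list. The classes were promoter, exon, intron, transcription termination site (TTS) and intergenic. Among peaks whose promoter gene was also the nearest gene, centres of the promoter class ran from -1000 to 100 bp around the TSS. A long peak of another class can therefore also cover a TSS. No read counts were used here, so the depth of the libraries is unknown. With 1 library per group there is no replicate error, and no test between conditions was possible. Every interval and p-value below treats peaks, which are not independent replicates, as the units and describes this list only.

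Coordinates are printed as the authors' list gives them. Peak length counts both end positions. Shares of peaks carry 95% Wilson intervals, which cover counting error only. Differences of median scores carry 95% bootstrap intervals (2000 draws over peaks) and two-sided permutation tests (100000 resamples, smallest possible p 1e-05), with Benjamini-Hochberg adjustment over the 7 comparisons made. Each such comparison was also made within 10 length strata, with 500 bootstrap draws, and its direction was counted on the 19 numbered chromosomes. Because the list gives a signed distance for each peak, the TSS position and strand were recovered for the 12847 genes with 2 or more peaks; 0 genes had peaks that fitted no single TSS. For the 7305 genes with 1 peak, the strand was drawn at random with a fixed seed, and the TSS position followed from that draw. Peak centres were then placed at random 1000 times between the first and the last peak of each sequence. TSSs of genes that the list does not name were not used, so random shares near a TSS are too low. Missing TSSs lower both terms of the ratio of peak density within 200 bp of a TSS to that from 1 to 2 kb away, so this ratio was compared instead. The placement test had been planned for a genome of the same build; with none used here, it was run on the TSSs recovered from the list. The functions were tested on simulated data. All 1373 simulated genes with 2 or more peaks got back their true TSS, 5% of 100 draws of 300 against 300 peaks with unchanged scores gave p under 0.05, and a shift of 4 score units did so in 100% of 100 draws. The simulated distances followed the rule that the recovery inverts, and the draws were independent, so these checks test the code only.

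Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Of the 20152 gene identifiers in the list, 0 matched the RefSeq gene table of 29591 genes used for names, and no genome sequence was used. Genes therefore keep their identifiers, of which only the 2 with the highest-scoring promoter peaks are printed, and other regions are given by position. The planned tests of gene families and of sequence motifs needed names or sequence and were not run, and neither was the comparison of class shares with the genome. The class shares, the position around the TSS, the comparison of promoter with intergenic scores and the counts per chromosome were fixed before the data were examined. The other 6 score comparisons, the matching on length, the gene-side counts, the parts of genes, the sides of intergenic peaks, the peaks per gene and the length of 3 kb for broad peaks were chosen after the data were seen. Peaks were also split at the score quartiles into 4 groups, of which only the use of the highest was planned. Alternatives covered subsets of peaks by score, length and chromosome, peak edges, random shifts, TSSs of genes with 2 or more peaks and other window sizes. The rule for named genes took the 10 highest-scoring promoter peaks of genes with a known function; with no names, the 10 were ranked without that condition. The 10 highest-scoring peaks of any class and the 10 longest were added after the data were seen.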

Results

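Binding of FLAG-tagged VlbZIP30, a basic leucine zipper (bZIP) transcription factor, was mapped by ChIP-seq in leaves of drought-stressed transgenic grapevine to find its targets during drought. The data were 1 anti-FLAG library and 1 IgG control library from plants that went without water for 20 days, from which the authors deposited 1 peak list. The samples analysed here held no replicate libraries, unstressed plants or plants without the tag, so the list was described by where its peaks lay and how strongly each was scored, and no effect of drought could be measured.

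The list held 49173 peaks, whose nearest genes numbered 20152. Peaks covered 38.4 Mb, or 7.94% of the 484 Mb spanned by the sequences, each counted up to the end of its last peak. The same spans were used for peaks per Mb below. The median peak length was 517 bp (quartiles 320 and 910 bp). The median peak score was 7.56 (quartiles 3.64 and 18.5, highest 205). Of all peaks, 94.4% lay on the 19 numbered chromosomes, 2194 peaks lay on the sequence named Un and 574 on 13 sequences named random. A promoter peak was found at 11907 genes, 480 of which had 2. Of these genes, 5007 also had a peak in an exon or intron and 3684 had a peak at the TTS.

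Intergenic and promoter peaks were the most frequent classes. Intergenic peaks made up 32.5% (95% interval 32.1 to 32.9%) and promoter peaks 25.2% (24.8 to 25.6%). Introns held 14.6% (14.3 to 14.9%), exons 14.5% (14.2 to 14.8%) and TTSs 13.2% (12.9 to 13.5%). Promoter shares ranged from 22.6% to 27.2% over the numbered chromosomes. The size of each class in the genome was not used here, so these shares are not enrichments.

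The make-up of the list differed with the score. In the highest-scoring quartile group (12253 peaks, median length 1069 bp), promoters held 36.0% (95% interval 35.2 to 36.9%) and introns 7.70% (7.24 to 8.18%). In the lowest-scoring quartile group (13101 peaks), promoters held 11.6% (11.04 to 12.1%) and introns 27.4% (26.7 to 28.2%). The promoter share was higher in the highest than in the lowest group on 19 of 19 numbered chromosomes.

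Promoter peaks scored highest, with a median of 12.8 (quartiles 5.98 and 25.4, n = 12387 peaks). Medians were 9.80 for intergenic peaks (n = 15989), 5.98 for TTS peaks (n = 6489), 4.53 for exon peaks (n = 7118) and 3.68 for intron peaks (n = 7190). The promoter median exceeded the intron median by 9.16 (95% interval 8.42 to 9.33) and the exon median by 8.32 (7.80 to 8.65). It exceeded the TTS median by 6.87 (6.35 to 7.41) and the intergenic median by 3.04 (2.48 to 3.54). Each of the 4 differences reached the smallest p that the permutations can give (two-sided permutation test, p = 1e-05, adjusted p = 1.4e-05) and had the same direction on 19 of 19 numbered chromosomes. Score and length were related across peaks, which are not independent replicates (Spearman rho 0.676), and with peaks matched on length the promoter excess over intergenic peaks fell to 0.476 (0.125 to 0.860), while that over intron peaks was 6.27 (5.77 to 6.63).

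**Figure D1:**
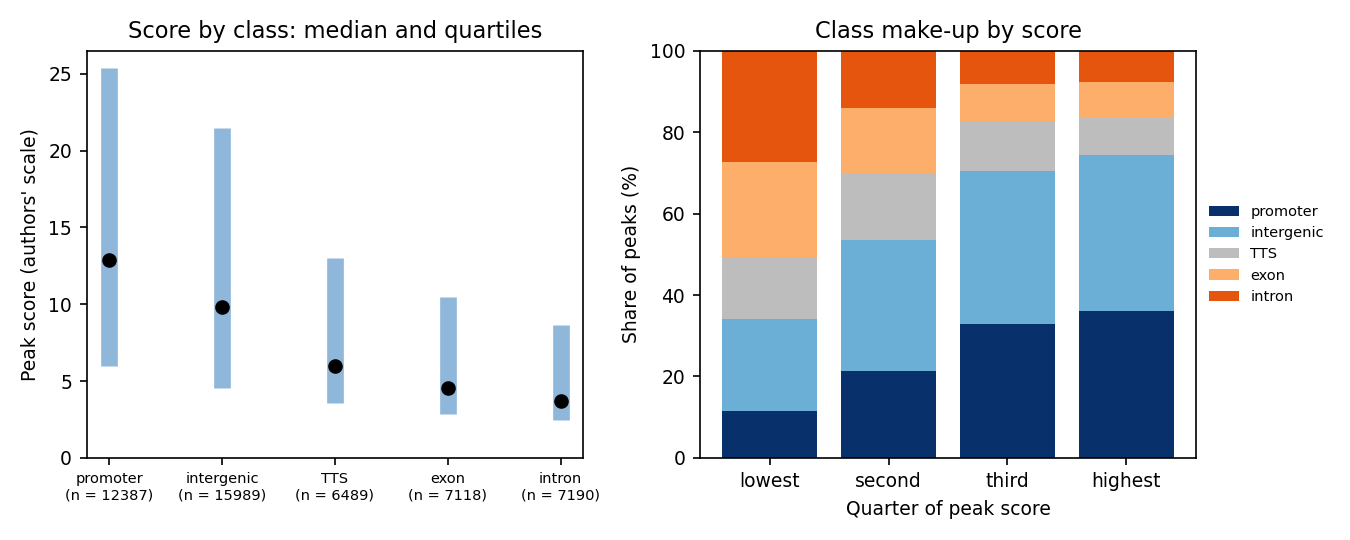
Left, peak score by annotation class on the authors' scale; points are medians and bars run from the lower to the upper quartile over peaks. Right, share of peaks (%) of each class in the 4 quartile groups of peak score, from lowest to highest; the promoter share rises from 11.6% to 36.0% and the intron share falls from 27.4% to 7.70%.

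Peak centres crowded at the TSS. Within 200 bp of a TSS lay 16.1% of the peaks and within 1 kb 36.3%. The densest 100 bp was the one just upstream of the TSS, with 2479 peaks, and the next 100 bp downstream held 2281. Peak density within 200 bp was 4.45 times that from 1 to 2 kb away. In 1000 random placements this ratio averaged 1.10 and reached at most 1.21 (one-sided permutation test by random placement, p = 0.001, the smallest the placements can give). The ratio was 6.37 times its random mean in the highest-scoring quartile group and 1.41 times in the lowest, against 4.04 times for all peaks. Measured from the nearest peak edge, 29.1% of peaks lay within 200 bp. Scores were highest from 200 to 500 bp upstream, with a median of 14.9 (n = 2964 peaks), and fell to 4.08 from 500 to 1000 bp downstream (n = 2526). Median peak lengths in these windows were 821 and 442.5 bp, and the windows were not matched on length.

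**Figure D2:**
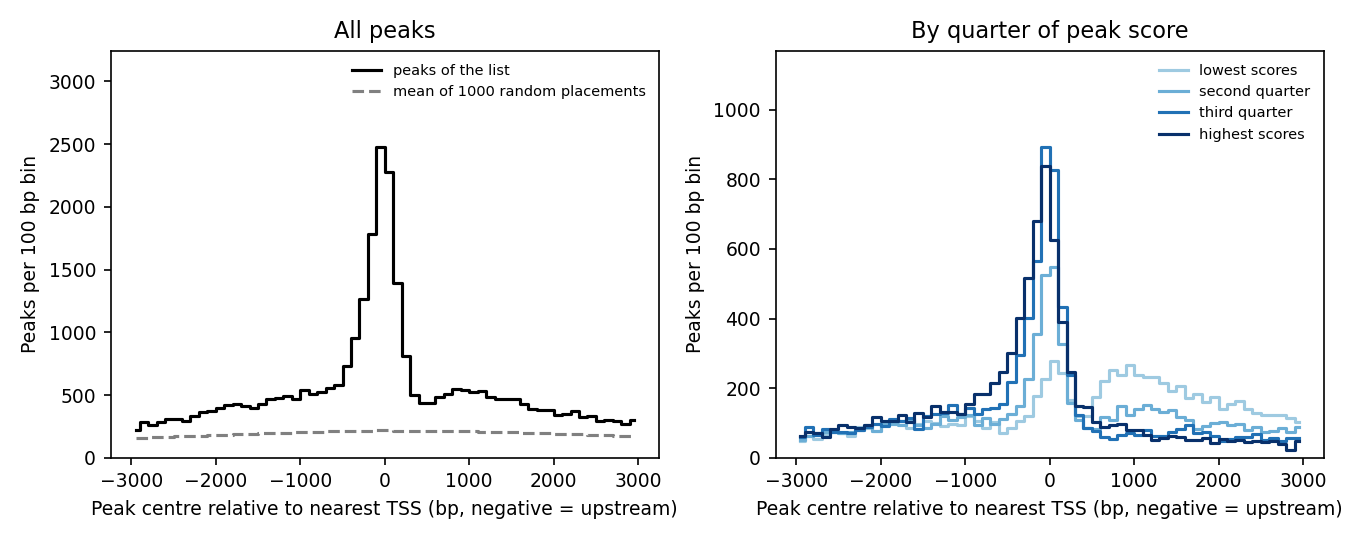
Number of peak centres per 100 bp against distance to the nearest TSS (bp, negative upstream), for all peaks with the mean of 1000 random placements (left) and for each quartile group of peak score (right). The highest bin of all peaks holds 2479 centres, and peaks of the lowest-scoring group rise again inside the gene, to 266 from 900 to 1000 bp.

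High-scoring and low-scoring peaks lay more often on opposite sides of the TSS. From 0.5 to 2 kb away, 32.2% (95% interval 30.6 to 33.8%) of the peaks in the highest-scoring quartile group lay on the gene side (1045 against 2203 upstream). In the lowest-scoring group, 68.2% (66.9 to 69.6%) did (3165 against 1473). Random placements gave 50.9% on average, with a range of 49.2 to 52.6% over 100 placements. The strand of genes with 1 peak was drawn at random, which by itself balances the 2 sides in these placements. The gene side held more peaks of the lowest group on 19 of 19 numbered chromosomes, and more of the highest group on 0 of 19.

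Within genes, peaks in first exons and first introns scored above those in later ones. In genes with 3 or more exons, exon peaks in the first exon had a median score of 8.12 (95% interval 7.56 to 8.68, n = 1225 peaks), against 4.08 in the last exon (n = 1613) and 3.63 (3.22 to 3.64, n = 2269) in inner exons. In genes with 3 or more introns, peaks in the first intron had a median of 5.02 (4.53 to 5.48, n = 1521). Medians were 3.64 in the last intron (n = 980) and 3.22 in inner introns (n = 3095). Peaks in first parts were also longer, with median lengths of 620 bp against 365 bp in inner exons and 462 bp against 343 bp in inner introns. With peaks matched on length, the first exceeded the inner parts by 5.63 (4.62 to 6.46) for exons and 2.77 (2.17 to 3.53) for introns. Exon and intron lengths were not used, so the counts of peaks per part are not densities. First exons and introns are also those nearest the TSS. Peaks were not matched on distance, so part of the gene and distance from the TSS cannot be told apart in these scores.

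Intergenic peaks were more often upstream of their nearest gene than beyond it. Of these peaks, 11706 (73.2%) lay upstream, at a median of 3122.5 bp from the TSS, and 4283 lay downstream, at a median of 5384 bp. A downstream position is separated from its TSS by the whole gene, which by itself lowers that share. Upstream intergenic peaks scored higher, with a median of 10.5 against 7.98, a difference of 2.47 (95% interval 2.10 to 2.94; two-sided permutation test, p = 1e-05, adjusted p = 1.4e-05). The direction was the same on 19 of 19 numbered chromosomes. Peaks were not matched on distance, so side and distance from the TSS cannot be told apart in this score difference.

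Among the 10 highest-scoring peaks, 5 were classed as promoter, 3 as exon, 1 as TTS and 1 as intergenic. The class does not describe the whole peak: each of the 3 exon peaks also spanned the TSS of its nearest gene. The highest score, 205, belonged to a peak of 1297 bp on chromosome 16 (16960714 to 16962010), in the promoter of VIT_16s0050g00120, whose plus-strand TSS lay 948 bp downstream of the peak centre at 16962310. The second, 203, was a peak of 3104 bp on chromosome 18 (9864931 to 9868034), centred in exon 1 of a gene with 2 exons. The third, 187, lay on chromosome 19 (9039589 to 9040470), 212 bp upstream of the TSS of VIT_19s0015g00930. A further promoter peak on chromosome 19 (17643629 to 17646608) scored 170.1 and was 2980 bp long. The highest-scoring intergenic peak, at 168, lay on chromosome 4 (8790165 to 8791744), 2521 bp upstream of a minus-strand TSS at 8788433. On chromosome 13, a promoter peak from 19070084 to 19071672 scored 154. Of the 10 highest-scoring peaks, 2 were on the sequence named Un, with scores of 148 (13862274 to 13863372, promoter) and 142 (30803813 to 30805944, exon 2 of 2). The remaining members of the 10 promoter peaks with the highest scores lay on chromosome 19 (4195635 to 4197067, score 128), chromosome 14 (8756146 to 8757056, 127), chromosome 10 (3103065 to 3105805, 126), chromosome 2 (988684 to 989550, 125) and chromosome 12 (8047604 to 8049241, 123).

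Some genes were nearest to many peaks. The median was 2 peaks per gene, and 2204 genes had 5 or more. The most was 17, reached by 2 genes. At the gene on chromosome 1 the peaks ran from 21402997 to 21430842, 13 of them intergenic, with a highest score of 37.8. At the gene on chromosome 18 they ran from 26025837 to 26049676, 10 of them intergenic, with a highest score of 49.0. The neighbouring stretch of chromosome 1, from 21324454 to 21398996, held 15 more peaks of another gene, with a highest score of 115.

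Peak density varied along and between chromosomes. It ran from 79.2 peaks per Mb on chromosome 15 to 155 on chromosome 8. The number of peaks per listed gene ran from 2.31 to 2.67. A gene is listed only if it has a peak, so this number has a floor of 1 and its divisor depends on the peaks. The range therefore does not show whether peak density follows gene density. The densest 1 Mb, on chromosome 16 from 21000001 to 22000000, held 327 peaks, or 0.665% of the list, against a median of 67.5 over 504 such windows with peaks.

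Peaks of 3 kb or more numbered 1202, and 65.6% of them (95% interval 62.8 to 68.2%) spanned a TSS. Length alone makes a long peak more likely to span a TSS. No random placement of such lengths was run, so this share is not an enrichment. They made up 4.84% of the peaks on chromosome 18 (4.20 to 5.57%), 3.80% on chromosome 1 (3.20 to 4.51%) and 1.04% on chromosome 16 (0.669 to 1.62%). The longest, of 17092 bp, lay on chromosome 1 (4465586 to 4482677), and 4 of the 10 longest lay on chromosome 18.

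**Figure D3:**
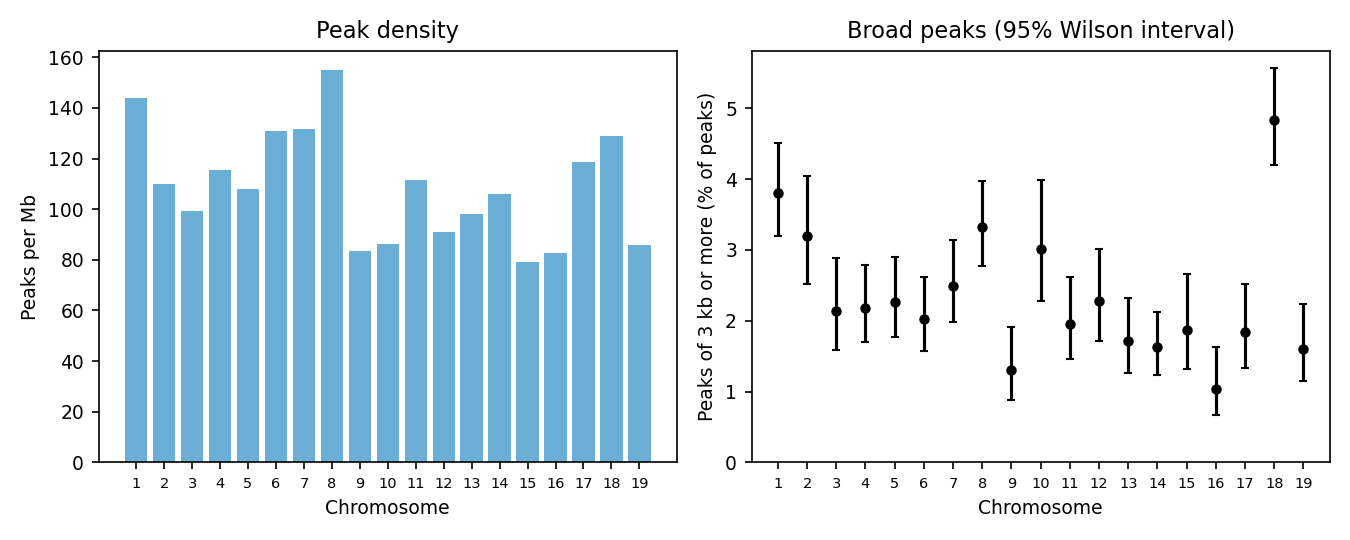
Left, peaks per Mb on each numbered chromosome, from 79.2 on chromosome 15 to 155 on chromosome 8. Right, share of peaks (%) that are 3 kb or longer, with 95% Wilson intervals over peaks; chromosome 18 stands highest at 4.84%.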

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

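Of 46 alternative values, 24 stayed within the interval or on the same side of the test and 22 moved, and 0 changed direction. Most of the moved values are shares or medians, which have no direction to change. The promoter excess over intergenic peaks, counted as staying on the same side, was 3.04 for all peaks and 0.476 matched on length. The score comparisons of promoters with TTS, exon and intron peaks, and the settings with the lowest-scoring quartile group, peaks under 1 kb, random shifts, TSSs of genes with 2 or more peaks, matching on length and other lengths of broad peaks, and, for scores, numbered chromosomes alone, were chosen after seeing the data. With the highest-scoring quartile group, the promoter share was 36.0%, intergenic 38.5%, TTS 8.96%, exon 8.85% and intron 7.70%, the share within 200 bp of a TSS 20.7%, the median length 1069 bp and the median score 31.9. With the lowest-scoring quartile group, the shares were 11.6%, 22.5%, 15.1%, 23.4% and 27.4%, with 7.11% within 200 bp. With peaks under 1 kb, promoters held 23.7%, intergenic space 33.8%, TTSs 12.1% and introns 15.9%. Measured from the nearest peak edge, 29.1% of peaks lay within 200 bp. The largest share in 1 window was 0.0976% with windows of 100 kb. The TSS density ratio was 4.04 times the random mean. It was 6.37 times with the highest and 1.41 times with the lowest quartile group, 4.09 times with random shifts and 3.10 times with genes of 2 or more peaks, each time above all of the 100 placements run for it. The excess of broad peaks on chromosome 18 over the other numbered chromosomes was 2.13-fold at 3 kb, 1.73-fold at 2 kb and 2.82-fold at 5 kb. The higher median score of the highest-scoring group and the smaller share of smaller windows follow from their definitions. The cause was not tested for the other moved values. The 4 differences between promoter and other scores stayed above 0 with numbered chromosomes alone, with length in place of the score and with peaks matched on length. Matching on length moved the excess of first over inner exons from 4.49 to 5.63 and that of first over inner introns from 1.80 to 2.77. No fold enrichment per peak was given, so that planned threshold was not run, and neither were the comparison with the genome and the motif and gene list alternatives. No paired analysis was possible because each group has 1 library, which also left no replicate to leave out. The depth of the libraries is unknown, so its effect on the number of low-scoring peaks was not tested.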

Other observations

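Genes with ENSRNA identifiers, a name that sets them apart from the VIT identifiers of most genes in the list, were named in promoter annotations at 222 genes and as the nearest gene at 372. Of the 710 peaks nearest to the latter, 33.2% lay in promoters. Peaks annotated to promoters of ENSRNA genes had a median score of 13.0 (n = 231), against 12.8 at VIT genes (n = 12156), a difference of 0.171 (95% interval -2.52 to 2.39; two-sided permutation test, p = 0.89, adjusted p = 0.89), and matched on length the difference was -1.56 (-3.32 to 0.386), so its sign stays open. The highest-scoring peak next to such a gene scored 107 and lay on chromosome 6 (17893006 to 17896315). Intergenic peaks more than 10 kb upstream of their nearest TSS numbered 1169, or 9.99% of the upstream ones. Those more than 10 kb downstream numbered 859, or 20.1% of the downstream ones.

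The tests below on random placement, peak length, untagged plants, extra copies, blocks of windows, chromosome midpoints and shared promoters were chosen or written down after the result each measures had been seen. The one on gene density was written down before its value was seen, although the excess on chromosome 18 was known. For shifted borders the order is not recorded. No biological difference between groups was tested as an explanation, since the 2 groups are the precipitation and its control. The crowding of peak centres at the TSS was first set against the way peaks are assigned to their nearest TSS. The observed density ratio of 4.45 exceeded the highest ratio of 1000 random placements, 1.21, so assignment alone does not account for it. In the lowest-scoring quartile group the ratio was 1.41 times the random mean.

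Promoter peaks scored above intron peaks. Longer peaks had higher scores, but the promoter excess over introns was 6.27 (95% interval 5.77 to 6.63) when peaks were matched on length, so length is not the whole cause. The unmatched difference was 9.16, but its gap to the matched value does not measure a part tied to length. Matching raised the excess of first over inner exons from 4.49 to 5.63, although peaks in first exons were longer. Precipitation at open promoters without the tagged protein may give the same ranking; with 0 libraries from plants without the tag, it cannot be told apart from binding by VlbZIP30.

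Peaks of 3 kb or more were frequent in the first 14 Mb of chromosome 18, a border chosen after the positions were seen, where they made up 5.82% of 3006 peaks, against 1.03% of 776 peaks beyond it. Merging of neighbouring peaks where genes are dense stays open: chromosome 18 had 1.87 times (95% interval 1.47 to 2.28) the 97.7 such peaks expected from other windows with a like number of listed genes, but a gene is listed only through its peaks, so merging itself lowers that number. Extra copies of the chromosome also stay open: its median score differed from that of the other numbered chromosomes by 0.554 (-0.0742 to 0.876) for all peaks and by -0.484 (-0.869 to -0.484) for peaks under 1 kb, a set that higher scores would change. The low share of 1.09% (0.554 to 2.14%) beyond the midpoint of chromosome 18 does not settle it, since 10 of the 36 stretches on either side of the midpoints of the other numbered chromosomes lay at or below it. Chance placement of regional clusters stays open too: 0% of 406 blocks of 30 windows of 1 Mb without chromosome 18 reached its share (highest 4.26%), but only 13 such blocks share no window, and a shift of all borders (77.5% as high) had kept the cluster of chromosome 18 itself.

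A shared promoter was considered as a candidate source of higher scores. The comparison had first been framed as a check on peak length and was reworded after its value was seen, so both values are given. The 419 peaks that lay in the promoter range of 1 gene and closer to the TSS of another had a median score of 13.9 against 12.7 for other promoter peaks, a difference of 1.11 (95% interval -1.34 to 3.72; two-sided permutation test, p = 0.23, adjusted p = 0.27). Matched on length, the difference was -1.22 (95% interval -2.30 to 0.347), so the test leaves its direction open. A peak in the promoter range of 2 genes counted among the others if its annotated gene was the nearer. The comparison therefore does not separate shared from unshared promoters and cannot show whether sharing raises scores.

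Inside the gene, the profile differed with the score. In the lowest-scoring quartile group, the bins of 100 bp from 300 to 500 bp downstream of the TSS held 119 and 119 peaks, against 253, 237 and 266 from 700 to 1000 bp. In the highest-scoring group, the same bins held 148 and 146 peaks, against 95, 96 and 81. The 2 groups also differed in length, with medians of 300 bp in the lowest and 1069 bp in the highest. Peaks under 500 bp, of any score, numbered 159 and 167 in these bins, against 298, 319 and 297. Score and length therefore cannot be told apart in this contrast.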
